A study of Homo sapiens with 9 samples.

How the data were processed

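Perturb-seq (single-cell RNA sequencing of cells that each carry guide RNAs, with the guides read from the same cells) was performed in EndoC-βH1, a human beta-cell line that secretes insulin. Per the labels, the cells expressed a repressor fusion of catalytically dead Cas9 with the KRAB domain of ZIM3 (CRISPR interference, which lowers transcription of a gene from its promoter), received a lentiviral guide library and were collected on day 14 after transduction. The 9 samples fell into 7 samples of a guide library that the labels call GWAS and 2 samples of a library that they call RQC. Guide names in the deposited feature tables gave 61 targeted genes, 204 targeting guides and 21 non-targeting guides in the GWAS library, and 40 targeted genes, 86 targeting guides and 14 non-targeting guides in the RQC library. The numbers in the sample titles served as replicate numbers.

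Each deposited matrix holds raw UMI counts per gene or guide and cell barcode, written by Cell Ranger 7.2.0 per the file headers, and GRCh38 and Seurat 4.3.0 appear in the submitters' processing notes without a stated role. The chemistry was 10x 3' version 3.1 with guides captured directly, per the labels' protocols. The matrices hold 36601 genes and only barcodes called as cells. The deposited feature and barcode tables hold names and no measured values. What "RQC" abbreviates is not given in the sources used here, and no guide sequence or position was used.

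Cells with at least 1000 detected genes and at most 20% of UMIs from mitochondrially encoded genes were kept. Guide UMIs were summed per targeted gene, with all non-targeting guides as 1 control target. A cell was assigned to the target with the most guide UMIs where these came to at least 5 and to at least 80% of the cell's guide UMIs. No doublet caller was run. Cells with 2 or more prominent targets, which include most doublets of differently targeted cells, stayed unassigned, whereas doublets that share a target cannot be seen this way. UMI counts were summed per sample and target (a pseudobulk), so that samples and not cells were the replicates, and sums of under 10 cells were left out.

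In the GWAS library each target was fitted with the control sums of the same samples, which needed at least 3 samples. In the RQC library, whose 2 samples leave too few degrees of freedom for separate fits, all targets shared 1 fit. Genes with a mean of at least 5 CPM (counts scaled to a common library total) in a fit were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) after TMM scaling, two-sided, with the sample as a block. This pairing came from the assay, since the target and control cells of a sample were captured and sequenced in the same 10x library. P-values were adjusted per target after Benjamini-Hochberg with a threshold of 0.05, and a gene past that threshold is said to have risen or fallen. A targeted gene was left out of the counts of its own target. DESeq2 1.42.0, limma 3.58.1 (voom), other scaling factors, other filters on cells, genes and guides, capped cell numbers, another reference, each sample left out in turn and fits without the block were alternatives. A further alternative, added after the data were seen, compared carriers (cells with at least 10 guide UMIs of a target, whatever else they carried) with carriers of a control guide. In the GWAS library cells that carried both were left out of both groups. In the RQC library they were left out of the target sums only, and a cell with several targets entered several sums of the shared fit. Whether guides of several targets in a cell come from several infections, several cells in a droplet or free guide RNA is not known, so that carriers can include cells without the guide's effect. Runs without the control guide with the most cells, and without GWAS replicates 5 and 6, were added in the same way. The same test was run for each non-targeting guide against the other non-targeting guides.

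Before the data were examined, 32 gene lists were fixed, with 934 entries, of which 908 matched by symbol, 22 through Ensembl identifiers or synonyms in a RefSeq gene table of GRCh38.p14, and 4 did not match. Lists with at least 5 tested members, without the targeted gene, entered edgeR's camera test with a preset correlation of 0.01, adjusted over all targets and lists of a guide library. The correlation estimated from the residuals and limma's fry were alternatives. Fry asks whether the genes of a list move 1 way on balance, and does not compare them with other genes.

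The rule for named genes was also fixed beforehand. It takes, per guide library, the 5 targeted genes with the largest fall and each one that did not pass. In the 8 targets with the most calls it takes the 3 largest rises and the 3 largest falls with a mean of at least 20 CPM and the same sign in each sample, and up to 4 members of each called list. It also takes a panel of 22 genes of hormone secretion, beta-cell identity and stress in any target where they passed. A few targets are counted in the totals but not reported by name here. Genes named outside this rule are marked as chosen after their values were seen.

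Similarity of targets with at least 20 calls was the Pearson correlation across genes called in any target of the library, with each target set against another of 2 disjoint random sets of control cells. The value with no effect was simulated 100 times from the shared controls. The targets present in both libraries were compared by an interaction of target and guide library. Genes within 100000 bases of the targeted gene were found with the RefSeq table, by Ensembl identifier, symbol or a synonym held by a single gene, from coordinates of the same build. Ratios of UMI sums have exact 95% intervals, and shares of cells exact binomial 95% intervals.

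The tests were checked on simulated counts drawn around the real means and depths, with 200 changed genes each. For the GWAS sums of PELO, the edgeR test recovered 79.1% of genes changed by 0.5 log2 and 100% of those changed by 1, with 12 false calls among 12417 genes. For the sums of ANKH, with fewer cells, it recovered 43.3% at 0.5, 88.1% at 1 and 100% at 2, with 3 false calls among 12342 genes. For the RQC sums of HBS1L it recovered 71.6% at 0.5 and 100% at 1, with 10 false calls among 12273 genes, and edgeR's camera called a raised list of 35 genes and 0% of 200 random lists. Each gene was drawn independently in this simulation. It therefore does not show how often camera calls lists whose genes vary together without an effect. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.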

Results

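Transcriptomes and guides were read from single cells of EndoC-βH1, a human beta-cell line, in which CRISPR interference repressed 1 gene or more per cell. The GWAS guide library was aimed at 61 genes, among them the diabetes genes KCNJ11, ABCC8 and SLC30A8, and was profiled in 7 samples. The RQC guide library was aimed at 40 genes, many of them known for splitting stalled ribosomes or degrading their products, and was profiled in 2 samples. The question for each target was which transcripts differed between cells with its guides and cells with non-targeting guides of the same samples. The GWAS samples held between 6423 and 8329 barcodes in replicates 1, 2, 3, 4 and 7, 3129 in replicate 6 and 709 in replicate 5. Their totals were 211964095, 203623083, 212059648, 201875428, 41682960, 144909010 and 198076628 UMIs in replicates 1 to 7. The RQC samples held 9917 and 10468 barcodes with 265622758 and 272402759 UMIs. Of 39898 GWAS cells past the filter, 68.9% carried guides of 2 or more targets, and 11975 could be assigned to 1 target, 779 of them to the control guides. Of 19911 RQC cells, 28.1% carried 2 or more targets, and 11730 were assigned, 1438 of them to the control guides. The median target had 174 assigned cells in the GWAS library and 236.5 in the RQC library. FOXA2 (8 cells), a transcription factor of the beta cell, was among the targets with too few cells to be tested, which left 59 GWAS targets with 4 to 7 samples each and 40 RQC targets with 2.

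Most targeted transcripts fell. In the GWAS library the largest falls were those of KCNK16, a potassium channel of islet cells, and CAMK2B, a calcium-dependent kinase. KCNK16 was at a ratio of 0.0137 to the control (95% counting interval 0.00165 to 0.0497, 2 UMIs in target cells, n = 6 samples). CAMK2B was at 0.0186 (0.00225 to 0.0675, 2 UMIs, n = 5), and the deubiquitinase gene MINDY1 at 0.0361 (0.0074 to 0.106, 3 UMIs, n = 5). COBLL1 was at -4.17 ± 0.262 log2 (SE, n = 6) and SND1 at -4.13 ± 0.171 (n = 6). Among RQC targets, TOM1 was at a ratio of 0.0315 (0.00646 to 0.0925, 3 UMIs, n = 2). EDF1, a sensor of collided ribosomes, was at -3.05 ± 0.0997 log2, N4BP2 at -3.01 ± 0.132, GTPBP1 at -2.99 ± 0.327 and RACK1 at -2.90 ± 0.0848. Of the 41 GWAS targets with a tested transcript 28 fell, or 36 when adjusted over the targets alone, with a median of 8.93% left among the 28. Of the 39 in the RQC library 32 fell, or 38 when adjusted over the targets alone, with a median of 18.6% left among the 32. Intervals and floors here and elsewhere cover counting error only.

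**Figure D1:**
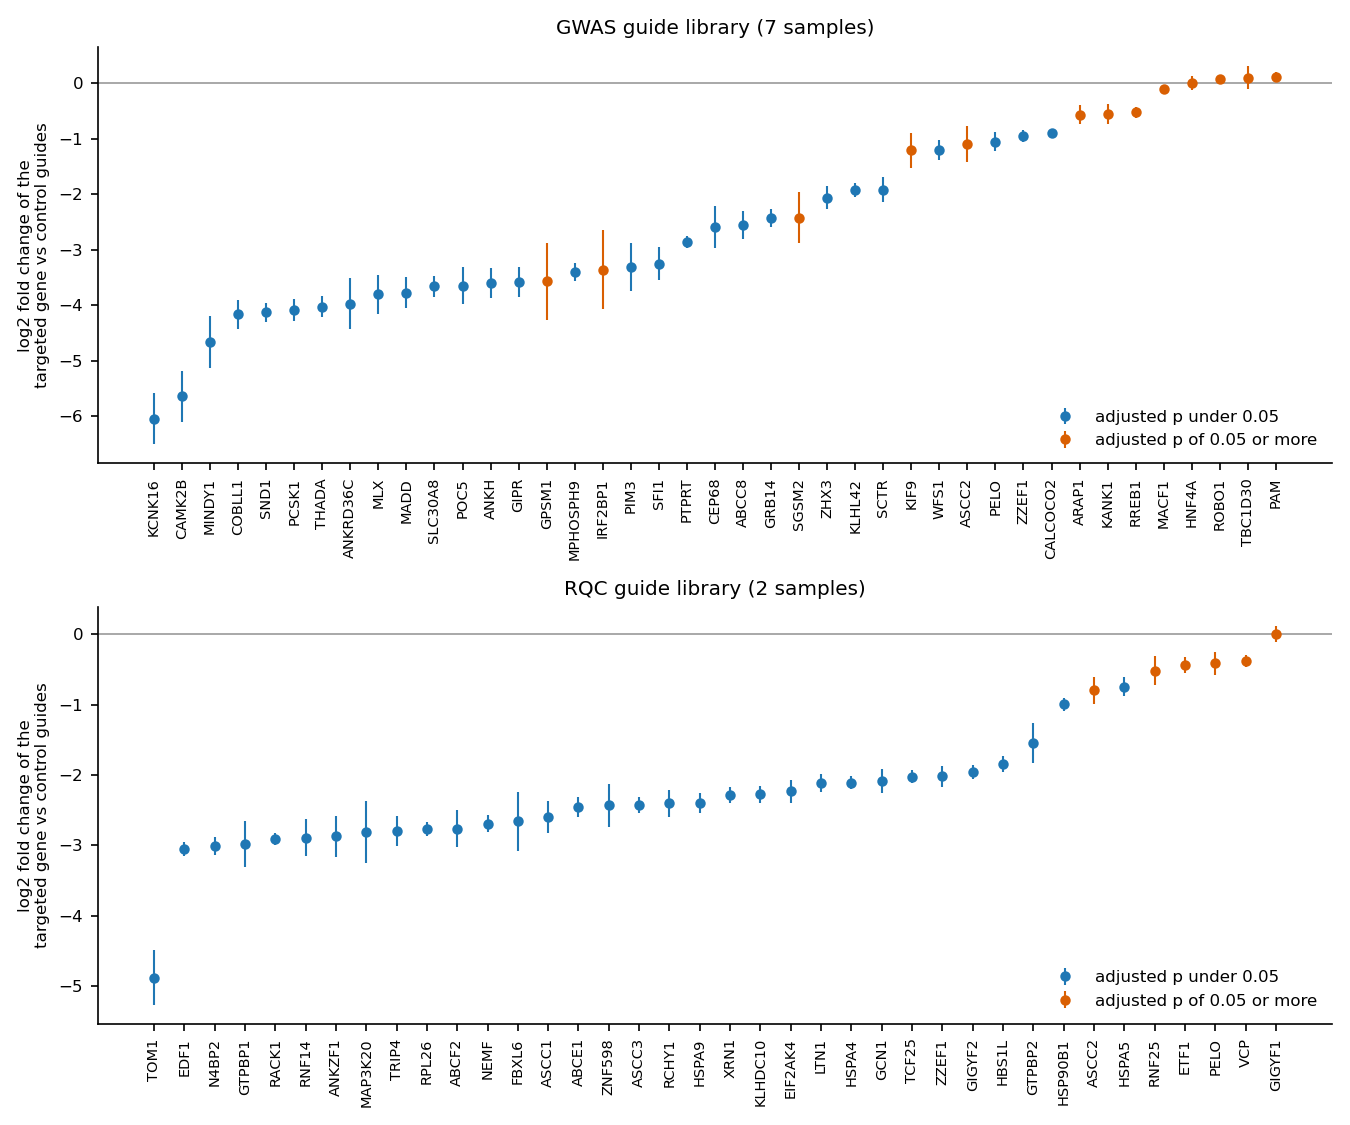
Log2 fold change of each targeted gene's own transcript in cells with its guides against control cells (vertical axis, error bars are SE), 1 point per tested target except 1 RQC target that is not shown, sorted along the horizontal axis, for the GWAS library above and the RQC library below. Blue points passed the test and orange points did not, and the medians over all tested targets are -2.59 in the GWAS library and -2.28 in the RQC library, with KCNK16, CAMK2B, MINDY1, IRF2BP1, GPSM1 and TOM1 resting on 2 or 3 UMIs each.

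The GWAS targets whose own transcript did not pass fell into those at a low level and those that stayed near the control. IRF2BP1 was at a ratio of 0.0895 (0.0108 to 0.327, 2 UMIs) and GPSM1 at 0.0756 (0.00909 to 0.277, 2 UMIs). SGSM2 was at -2.42 log2, KIF9 at -1.21 and ASCC2 at -1.09. ARAP1 (-0.57), KANK1 (-0.56), RREB1 (-0.52), MACF1 (-0.11), HNF4A (0.01), ROBO1 (0.07), TBC1D30 (0.10) and PAM (0.12) were closer to the control. In the RQC library those that did not pass included ASCC2 (-0.80), RNF25 (-0.52), ETF1 (-0.44), PELO (-0.41), VCP (-0.38) and GIGYF1 (0.00). For RNF25 the guides differed, with guide 1 at -2.44, 0 UMIs of RNF25 with guide 2 (104 cells), guide 3 at -0.03 and guide 4 at 0.31, and for ETF1 the guides were at -0.93 and 0.26, values per guide being chosen after they were seen. A further 18 GWAS transcripts and 1 RQC transcript, at most at 8.42 and 0.290 CPM in control cells, were under the filter. Of these, PLCB3 was at least 6.16-fold lower and TPCN2 at least 2.91-fold, with 0 UMIs in target cells and a floor of 3 counts over the group. In the same way WSCD2 was at least 7.35-fold lower, or at least 3.18-fold without replicate 4, which held 57 of its 108 control UMIs. The channel subunit KCNJ11 was at a ratio of 0.0909 (0.00228 to 0.520, 1 UMI).

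Some transcripts encoded beside a targeted gene fell with it. ANAPC10, a subunit of the ubiquitin ligase of mitosis, overlaps ABCE1 and fell by 2.65 ± 0.173 log2 in ABCE1 cells (n = 2). ANAPC16, of the same ligase, overlaps ASCC1 and fell by 2.38 ± 0.0960 in ASCC1 cells. ATG9A, a lipid scramblase of autophagy, starts 170 bases from ANKZF1 and fell by 2.22 ± 0.254, and the riboflavin transporter SLC52A2 lies 80 bases from FBXL6 and fell by 2.89 ± 0.269. ITGA1, which overlaps PELO, fell by 0.92 ± 0.147 in the GWAS library (n = 6) and fell by 0.84 ± 0.161 in the RQC library. CYB5D2, 138 bases from ZZEF1, fell by 0.80 ± 0.118 in the GWAS library and fell by 1.40 ± 0.165 in the RQC library. C12orf65, which overlaps MPHOSPH9, fell by 2.57 ± 0.214 in MPHOSPH9 cells (n = 6). Of 319 tested genes within 100000 bases of a target 13 fell, where the rate of other genes gives 0.847, and 0 rose (edgeR, and 0 in DESeq2, with 16 higher at an unadjusted p under 0.05 in edgeR). These genes were found by position after the calls were seen, and for the overlapping ones reads of the 2 genes cannot always be told apart.

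In the GWAS library 441 pairs of target and gene passed, 161 higher and 280 lower, and 361 of them (81.9%) belonged to MADD, ANKH, GIPR and CEP68. At least 1 gene passed in 35 of the 59 targets. Without replicate 2 the total was 219, and without replicate 4 it was 257. DESeq2 gave 570, and cells that carried a target's guides whatever else they carried gave 2857, of which 2623 belonged to MADD. P-values here and below measure the spread between samples, which come from 1 cell line. In the RQC library, where all targets shared 1 fit, this spread was pooled over the targets and was not measured for each target alone. The labels do not say whether the numbered samples are separate transductions or repeated captures of 1 transduced population, and in the latter case this spread is technical only.

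**Figure D2:**
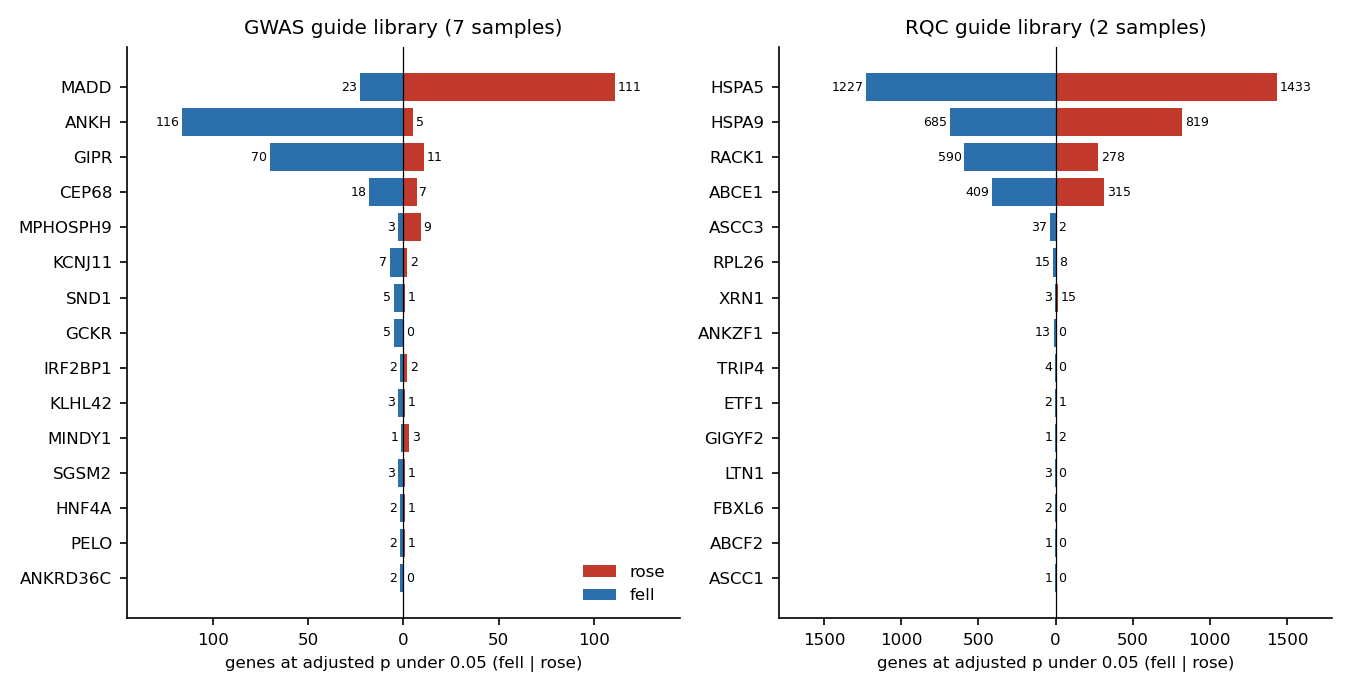
Number of genes that fell (bars to the left) and rose (bars to the right) at an adjusted p under 0.05 (horizontal axis) in the targets with the most calls of each guide library (vertical axis), with separate scales per library. In the GWAS library MADD (111 rose, 23 fell) and ANKH (5 rose, 116 fell) lie at the top, and in the RQC library HSPA5 (1433 rose, 1227 fell) and HSPA9 (819 rose, 685 fell).

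MADD, an exchange factor for Rab3 GTPases that act in exocytosis, had 111 genes higher and 23 lower (302 cells, n = 6 samples). Vitronectin (VTN) rose by 1.11 ± 0.199 log2 (adjusted p = 0.0216, edgeR), the matrix protein gene THSD4 by 1.08 ± 0.194 and the cortisol carrier SERPINA6 by 0.84 ± 0.146, each in 6 of 6 samples. The cell adhesion gene NEGR1 fell by 0.98 ± 0.173 and the kinase gene DCLK2 fell by 0.62 ± 0.123. Genes of protein synthesis and respiration rose by less. Of 79 cytosolic ribosomal proteins 23 rose, or 73 when adjusted over the list alone, with RPL15 at 0.33, RPL5 at 0.30 and RPS7 at 0.29 and a list median of 0.21. Of 55 nuclear-encoded genes of oxidative phosphorylation 10 rose, or 34 over the list alone, with NDUFC2 at 0.45 ± 0.0620 and SDHD at 0.40. Of 31 proteasome subunits 2 rose, or 7 over the list alone, among them PSMB1 at 0.37. All of these lists were at adjusted p = 0.956 with an estimated correlation. B2M, the light chain of HLA class I, rose by 0.40 ± 0.0517 (adjusted p = 0.00375), and the fatty acid desaturase SCD fell by 0.28 ± 0.0580. In cells carrying MADD guides whatever else they carried, 122 of the 134 genes also passed, with VTN at 0.88, NDUFC2 at 0.34 and B2M at 0.44. Fewer genes passed without replicate 7 (6), replicate 4 (7), replicate 3 (15) or replicate 2 (71), and edgeR called 0 with at most 150 cells per target (1190 at an unadjusted p under 0.05, where 627.6 are expected).

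ANKH, a transporter that exports pyrophosphate, GIPR, the receptor of the incretin GIP, and CEP68, a centrosome protein, shared lower mitotic transcripts. In ANKH cells (108 cells, n = 6) KIF18A, a kinesin of chromosome alignment, fell by 2.95 ± 0.347 log2 and ASPM, a spindle pole protein, fell by 2.82 ± 0.295. In GIPR cells (147 cells, n = 6) cyclin B1 (CCNB1) fell by 2.34 ± 0.261 and the ubiquitin-conjugating enzyme UBE2C fell by 1.86 ± 0.175. In CEP68 cells (71 cells, n = 4) UBE2C fell by 2.31 ± 0.401, the centromere kinesin CENPE fell by 4.28 ± 0.492 and ARHGAP11A fell by 2.14 ± 0.317, and CDC20 was at a ratio of 0.0431 (0.00109 to 0.243, 1 UMI). Of 51 G2/M genes 35 fell in ANKH, 31 in GIPR and 10 in CEP68, or 45, 46 and 44 when adjusted over the list alone, with medians of -1.59, -0.99 and -1.52. Each was at adjusted p = 0.956 with an estimated correlation. Cells with at least 0.3% of their UMIs from the G2/M list were counted among all assigned cells. They made up 9.91% of ANKH cells (11 of 111), 12.9% of GIPR cells (19 of 147) and 12.2% of CEP68 cells (10 of 82). The share was 17.1% of control cells (exact binomial 95% interval 14.5 to 19.9), and no interval was computed for the 3 targets. Other targets had shares as low, among them IRF2BP1 (9.76%) and KANK1 (10.2%), which were chosen after their values were seen, and carriers of ANKH, GIPR and CEP68 were at 17.3%, 17.2% and 17.4%. The median of the list was below 0 in 49 of the 59 targets against the control guides, and in 30 against all other assigned cells. In all, 116 of 121 called genes were lower in ANKH, 70 of 81 in GIPR and 18 of 25 in CEP68. Higher genes included DOCK5 (1.18 ± 0.186) and TM4SF4 (0.72 ± 0.154) in ANKH, PTGS2, the inducible cyclooxygenase, in GIPR (0.58 ± 0.118) and the zinc transporter of insulin granules SLC30A8 in CEP68 (0.87 ± 0.115). The alpha-cell genes IRX2 (-0.98 ± 0.181) and GC (-0.90 ± 0.169) fell in GIPR, 2 of the 11 tested markers of other islet cells. In cells carrying the guides whatever else they carried the G2/M medians were -0.22, -0.31 and -0.26, with the own transcripts at -2.05, -1.99 and -1.48 against -3.60, -3.57 and -2.59 in assigned cells, and edgeR called 0 genes in ANKH (652 at an unadjusted p under 0.05, where 627.65 are expected), 0 in GIPR (716, where 628.2 are expected) and 3 in CEP68. Single left-out samples moved the ANKH count to 43 (replicate 2), 64 (replicate 4) and 66 (replicate 6), the GIPR count to 24 (replicate 2) and 39 (replicate 3), and the CEP68 count to 2 (replicate 1), 1 (replicate 2), 127 (replicate 3) and 1 (replicate 7). The CEP68 count was also 1 with no replicate block or the stricter guide call. With limma-voom 4 genes passed in ANKH, 1 in GIPR and 2 in CEP68, each of them higher, so that none of the lower mitotic genes passed in that test.

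**Figure D3:**
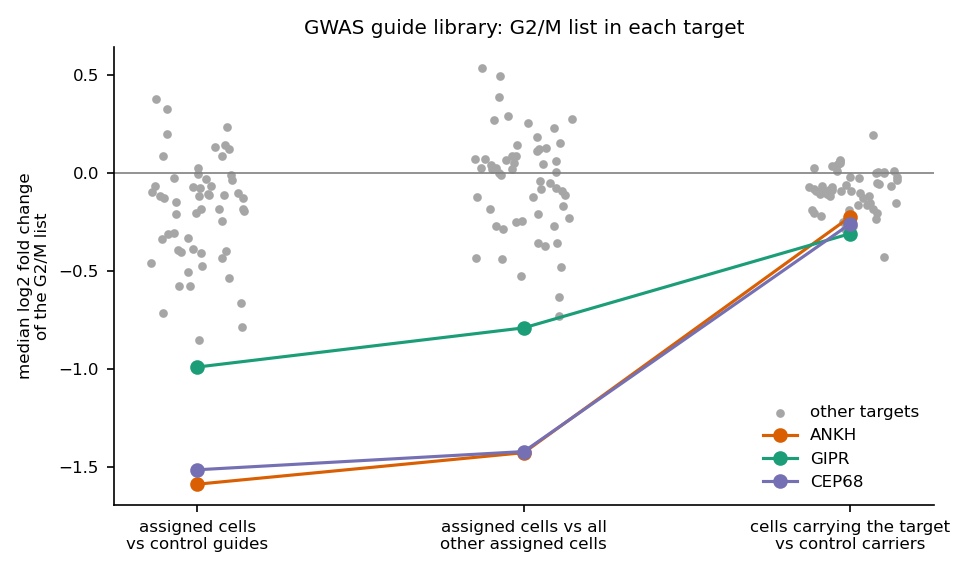
Median log2 fold change of the G2/M list (vertical axis) in each GWAS target, shown as points for assigned cells against control guides, for assigned cells against all other assigned cells and for cells carrying the target against control carriers (horizontal axis), with ANKH, GIPR and CEP68 as colored lines and the other targets in grey. ANKH, GIPR and CEP68 lie at -1.59, -0.99 and -1.52 on the left and at -0.22, -0.31 and -0.26 on the right.

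MPHOSPH9, a protein of the centriole and cilium base, was followed by higher mitochondrially encoded transcripts (202 cells, n = 6). MT-ND2 rose by 0.76 ± 0.0726 log2 (adjusted p = 7.89e-05, edgeR), MT-ND3 by 0.73 ± 0.0662, MT-ND1 by 0.58 ± 0.0658 and MT-ATP6 by 0.58 ± 0.0698, all in 6 of 6 samples. Of 13 such transcripts 8 rose, or 11 when adjusted over the list alone (median 0.38, adjusted p = 0.956 with an estimated correlation). C12orf65, a release factor that rescues mitochondrial ribosomes and whose gene overlaps MPHOSPH9, fell by 2.57 ± 0.214. The adhesion gene ALCAM fell by 0.57 ± 0.0988 and PDE4B, a phosphodiesterase of cyclic AMP, fell by 0.54 ± 0.0894. In cells carrying the guides whatever else they carried MT-ND2 was at 0.55, C12orf65 at -1.45 and ALCAM at 0.03, and 9 of the 12 genes also passed. Without replicate 1 the test gave 7 genes, without replicates 2, 3, 4 or 7 it gave 5, 6, 6 and 5, and with no replicate block it gave 6 (5 of the 12 among them) and with at most 150 cells 7.

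KCNJ11, the pore of the ATP-sensitive potassium channel, had 9 called genes (94 cells, n = 5), SND1, an RNA-binding nuclease, 6 (238 cells, n = 6) and GCKR, the regulator of glucokinase, 5 (104 cells, n = 5). In KCNJ11 cells the vesicle calcium sensor SYT1 rose by 1.68 ± 0.240 log2, and somatostatin (SST) fell by 2.47 ± 0.402 and SGCZ fell by 1.59 ± 0.233. In carriers SYT1 was at 0.27, SST at -0.83 and SGCZ at -0.49, and 1 of the 9 genes also passed, and with the looser guide call edgeR called 0 (570 at an unadjusted p under 0.05, where 625.4 are expected). In SND1 cells HACD3, an enzyme of very long fatty acid synthesis, fell by 0.61 ± 0.0661 (adjusted p = 0.00016, edgeR) and the signal peptidase subunit SEC11A fell by 0.37 ± 0.0647, and these were at -0.46 and -0.33 in carriers. In GCKR cells the duct keratin KRT19 fell by 1.31 ± 0.218 and was at 0.08 in carriers. GCKR itself had 3 UMIs in 708 control cells and 0 in the target cells, so that its knockdown could not be measured. DESeq2 called 0 genes in GCKR cells, where edgeR had 523 genes at an unadjusted p under 0.05. There edgeR called 0 with no replicate block (732 at an unadjusted p under 0.05) and 0 without the guide with the most cells (633), and limma-voom called 0 (570). Without replicate 3 the counts were 5 in KCNJ11 and 1 in GCKR, without replicate 4 they were 17 and 1, and without replicate 7 they were 5 and 1, and GCKR had 3 without replicate 1 or replicate 2.

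IAPP, the amyloid peptide released with insulin, fell in 6 targets. It was at -3.89 ± 0.320 log2 in KCNJ11, -3.08 ± 0.372 in GCKR, -3.92 ± 0.598 in IRF2BP1, -1.97 ± 0.252 in C17orf58 and -1.53 ± 0.285 in MADD, and was at a ratio of 0.0197 (0.00238 to 0.0712, 2 UMIs) in HNF4A, whose own transcript was at 0.01 ± 0.125. In carriers it was at 0.34 in KCNJ11, 0.30 in IRF2BP1 and 0.10 in MADD, and at -0.40 in GCKR, -0.44 in HNF4A and -0.27 in C17orf58, and passed in none of the 6. Of the 1153 IAPP UMIs in control cells, 40.3% came from guide Non-Targeting-13, which had 117 of those 779 cells. GAST, the gastrin gene, passed in 10 targets and LINC01924 in 9, both only lower, and AC060765.1 in 4, only higher, 3 genes chosen after their values were seen. Guide Non-Targeting-4, with 17.3% of control cells, held 54.4% of control GAST UMIs and 41.5% of those of LINC01924, and Non-Targeting-20, with 6.93% of cells, held 47.8% of those of AC060765.1. With all other assigned cells as the reference, IAPP passed in 5 targets and was at -4.02 in KCNJ11, -3.06 in GCKR, -3.73 in IRF2BP1, -1.93 in C17orf58 and -1.43 in MADD, each within its standard error of the value against the control guides. GAST passed in 7, and its change was smaller by 1.08 to 1.37 log2 in the 10 targets. At an unadjusted p under 0.05 (edgeR) with that reference stood IAPP in 29 and GAST in 27 of 59 targets, more than the 5% expected by chance. Shifts of these 2 genes were thus not limited to the targets in which they passed. AC060765.1 passed in 0 of 31 (edgeR, 8 at an unadjusted p under 0.05), and was at 0.82 to 1.45 log2 in its 4 targets, against 2.67 to 3.24 with the control guides. LINC01924 was under the filter in its 9 targets with that reference and could not be tested there.

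In 24 GWAS targets edgeR called 0 genes beyond the target's own, with between 438 and 757 genes at an unadjusted p under 0.05 where about 624 to 628 are expected. DESeq2 called 31 genes over 15 of these targets, and edgeR 95 over 10 of them in carriers. They include ABCC8, the regulatory subunit of the ATP-sensitive potassium channel, whose own transcript fell by 2.56 ± 0.253 log2 (142 cells, n = 6), and PAM, the peptide-amidating enzyme, whose own transcript did not pass. The zinc transporter SLC30A8 and the prohormone convertase PCSK1 had 2 and 1 called genes, although their own transcripts fell (-3.66 ± 0.187 and -4.09 ± 0.196). These targets were chosen for mention after their values were seen.

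In the RQC library 5874 pairs passed, 2875 higher and 2999 lower, of which 5756 (98.0%) belonged to HSPA5, HSPA9, RACK1 and ABCE1. At least 1 gene passed in 23 of 40 targets, and DESeq2 gave 4553 pairs. With adjustment over all targets together 2977 pairs passed, without the guide with the most cells of each target 2613, and with each target fitted alone with the control 8840. With 2 samples, leaving out either sample leaves no test.

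HSPA5 (BiP), the main chaperone of the endoplasmic reticulum, lost part of its own transcript (-0.74 ± 0.134 log2, 136 cells, n = 2), and 1433 genes were higher and 1227 lower. The proapoptotic factor DDIT3 (CHOP) rose by 3.85 ± 0.151 (adjusted p = 2.19e-28, edgeR), the disulfide isomerase PDIA4 by 3.37 ± 0.129 and the transcription factor CEBPB by 3.19 ± 0.129, in 2 of 2 samples. Of 30 genes of reticulum chaperones and the unfolded protein response 29 rose (median 1.70, adjusted p = 1.79e-08 with an estimated correlation), all 29 also when adjusted over the list alone. HERPUD1, a factor of reticulum-associated degradation, rose by 2.96 ± 0.125 and HYOU1, a chaperone of the same compartment, by 2.85 ± 0.0958. Of 31 targets of ATF4, the factor of the integrated stress response, 26 rose (26 over the list alone, median 1.33, adjusted p = 2.98e-07 with an estimated correlation), among them the cystine carrier SLC7A11 at 4.21 ± 0.253, TRIB3 at 2.69 and CHAC1, which degrades glutathione, at 2.66. Of 17 cytosolic tRNA synthetases 10 rose (10 over the list alone, adjusted p = 0.0003 with an estimated correlation), led by WARS at 2.28. Of 18 targets of NRF2, the factor of oxidative stress, 8 rose (10 over the list alone, adjusted p = 0.0352 with an estimated correlation), as did 12 of 47 ribosome quality control and collision factors (12 over the list alone, adjusted p = 0.0430 with an estimated correlation), including the small modifier UFM1 at 1.22 and VCP, which extracts proteins for degradation, at 0.80.

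Genes of the cell cycle and of the beta cell fell in HSPA5 cells. Of 41 S phase genes 36 fell (38 over the list alone), among them RRM2, a subunit of ribonucleotide reductase, at -2.36 ± 0.282, and of 52 G2/M genes 47 fell (50 over the list alone), among them the kinesin KIF11 at -2.26 ± 0.428. These lists were at adjusted p = 0.0510 and p = 0.587 with an estimated correlation. Of 23 beta-cell transcription factors 12 fell (13 over the list alone, adjusted p = 0.0670 with an estimated correlation), including MAFA at -0.58 ± 0.166, PDX1 at -0.52 ± 0.140 and NEUROD1 at -0.47 ± 0.0772. Insulin (INS) fell by 0.39 ± 0.0774, the granule protein CHGA fell by 0.70 ± 0.0754 and SLC30A8 fell by 0.88 ± 0.130. Of 79 cytosolic ribosomal proteins 46 rose (56 over the list alone, median 0.19, adjusted p = 0.799 with an estimated correlation). In carriers 2548 genes passed, of which 2046 are among the 2660, and adjustment over all targets left 1308.

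HSPA9, the HSP70 chaperone of the mitochondrial matrix, fell by 2.40 ± 0.143 log2 (103 cells, n = 2), with 819 genes higher and 685 lower. CEBPB rose by 3.52 ± 0.134, DDIT3 by 3.16 ± 0.163 and TRIB3 by 2.89 ± 0.162, and 23 of 31 ATF4 targets rose (25 over the list alone, median 1.20, adjusted p = 3.36e-08 with an estimated correlation). Of 13 mitochondrially encoded transcripts 11 fell and 1 rose (11 and 1 over the list alone, median -0.60, adjusted p = 0.0430 with an estimated correlation), with MT-ND6 at -1.25 ± 0.160 and MT-CO1 at -0.81 ± 0.0607. Of 18 NRF2 targets 11 rose (12 over the list alone, adjusted p = 1.28e-06 with an estimated correlation), among them the ferritin chain FTL by 1.99 ± 0.105 and NQO1, a quinone reductase, by 1.57 ± 0.268. Of 79 ribosomal proteins 77 rose (78 over the list alone, median 0.51, adjusted p = 0.0108 with an estimated correlation), with RPS12 at 0.88. The noncoding hosts of small nucleolar RNAs GAS5 (1.73 ± 0.0891) and SNHG12 (1.58 ± 0.197) rose, in a list of 28 nonsense-mediated decay targets and factors of which 10 rose and 2 fell (11 and 3 over the list alone, adjusted p = 0.0299 with an estimated correlation). Of 17 tRNA synthetases 10 rose (10 over the list alone, adjusted p = 1.18e-05 with an estimated correlation), and of 27 lysosome and autophagy genes 11 rose and 1 fell (14 and 1 over the list alone, adjusted p = 0.00546 with an estimated correlation), including the autophagy receptor SQSTM1 at 1.20. INS fell by 0.62 ± 0.0776 and the thioredoxin inhibitor TXNIP fell by 1.33 ± 0.232. Of 52 G2/M genes 37 fell (47 over the list alone, median -1.27, adjusted p = 0.587 with an estimated correlation), including the proliferation marker MKI67 at -2.08 ± 0.457. In carriers 2268 genes passed, 1244 of them among the 1504, whereas 649 passed with adjustment over all targets and 495 without the guide with the most cells.

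RACK1, a protein of the small ribosomal subunit, and ABCE1, the ATPase that splits ribosomes after termination, shared lower ribosomal protein transcripts. In RACK1 cells (310 cells, n = 2) RPL5 fell by 0.88 ± 0.0741 log2 and RPS4X fell by 0.85 ± 0.0778, and 72 of 79 ribosomal proteins fell (76 over the list alone, median -0.47, adjusted p = 0.00547 with an estimated correlation). In ABCE1 cells (236 cells, n = 2) RPS23 fell by 0.99 ± 0.0607 and RPS21 fell by 0.97 ± 0.0604, and 76 of 79 fell (78 over the list alone, median -0.66, adjusted p = 0.000188 with an estimated correlation). The elongation factor EEF1A1 fell in ABCE1 cells, at -1.50 ± 0.0645 (adjusted p = 9.43e-26, edgeR), and the mitochondrial uncoupler UCP2 fell by 1.39 ± 0.184, while the respiratory chain subunit NDUFA4 rose by 1.16 ± 0.114. RACK1 cells also had lower oxidative phosphorylation genes (36 of 55, 41 over the list alone, adjusted p = 0.0252 with an estimated correlation), such as COX4I1 at -0.57 ± 0.0633, and lower proteasome subunits (12 of 31, 20 over the list alone, adjusted p = 0.0325 with an estimated correlation), such as PSMB1 at -0.70 ± 0.0872. In RACK1 cells the beta-cell factors PDX1 (0.43 ± 0.111) and NKX2-2 (0.45 ± 0.102) rose. In ABCE1 cells 11 of 25 genes of cholesterol synthesis and uptake fell (18 over the list alone, adjusted p = 0.0500 with an estimated correlation), including FDPS at -0.76 ± 0.0856, and 12 of 31 reticulum chaperones (17 over the list alone, adjusted p = 0.0523 with an estimated correlation), including SDF2L1 at -0.99 ± 0.144. INS fell by 0.56 ± 0.0775 in ABCE1 cells. ANAPC10, which overlaps ABCE1, fell by 2.65 ± 0.173 in the same cells, so that effects of the 2 genes were not separated. With at most 150 cells per target 500 genes passed in RACK1 and 365 in ABCE1, without the guide with the most cells 165 and 81, with adjustment over all targets 437 and 359, and in fits of the target and control alone 1952 and 1622.

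ASCC3, the helicase that pulls collided ribosomes apart, fell by 2.43 ± 0.110 log2 (225 cells, n = 2), and 37 genes were lower and 2 higher. SRPRA, the receptor for the signal recognition particle, fell by 0.84 ± 0.149, CCDC47, a chaperone of membrane protein insertion, fell by 0.78 ± 0.0928 and HSPA5 fell by 0.76 ± 0.127. Of 31 reticulum chaperones and unfolded protein response genes 10 fell (15 over the list alone, median -0.30, adjusted p = 0.000176 with an estimated correlation), among them DNAJC3, HYOU1 and HSP90B1. Of 27 hormones and granule proteins 4 fell (6 over the list alone, adjusted p = 0.00547 with an estimated correlation), namely CHGA at -0.79 ± 0.0750, SCG3 at -0.68 ± 0.0653, INS at -0.47 ± 0.0774 and the carboxypeptidase CPE at -0.38 ± 0.0696. In carriers 34 of the 39 also passed, and 14 passed with at most 150 cells per target or 13 without the guide with the most cells.

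RPL26, XRN1 and ANKZF1 had 23, 18 and 13 called genes (191, 314 and 254 cells, n = 2). In RPL26 cells, with less of a large-subunit protein, the ribosomal proteins RPL10A and RPL23 fell (-0.45 ± 0.0762 and -0.43 ± 0.0724), as did 5 of 78 in all (25 over the list alone, adjusted p = 0.732 with an estimated correlation), and HMGCS1, an enzyme of cholesterol synthesis, fell by 0.54 ± 0.0943. In cells with less XRN1, the 5' exonuclease that degrades mRNA, ATF4 rose by 0.89 ± 0.0896 log2 (adjusted p = 5.31e-10, edgeR), the chromatin reader BRD2 by 0.65 ± 0.0773 and SNHG12 by 0.83 ± 0.159. Of 28 nonsense-mediated decay targets and factors 2 rose, or 13 when adjusted over the list alone (median 0.23, adjusted p = 4.82e-05 with an estimated correlation). In cells with less ANKZF1, which frees nascent chains from stalled ribosomes, the replication genes CDC6, DSCC1, PCLAF and UHRF1 fell, at -1.13 ± 0.204, -1.08 ± 0.201, -1.02 ± 0.209 and -0.97 ± 0.209. Of 41 S phase genes 7 fell, or 29 over the list alone (median -0.43, adjusted p = 0.00157 with an estimated correlation). ATG9A, beside ANKZF1, also fell in these cells, by 2.22 ± 0.254, so that effects of the 2 genes were not separated. With at most 150 cells per target 2 genes passed in RPL26, 6 in XRN1 and 1 in ANKZF1.

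**Figure D4:**
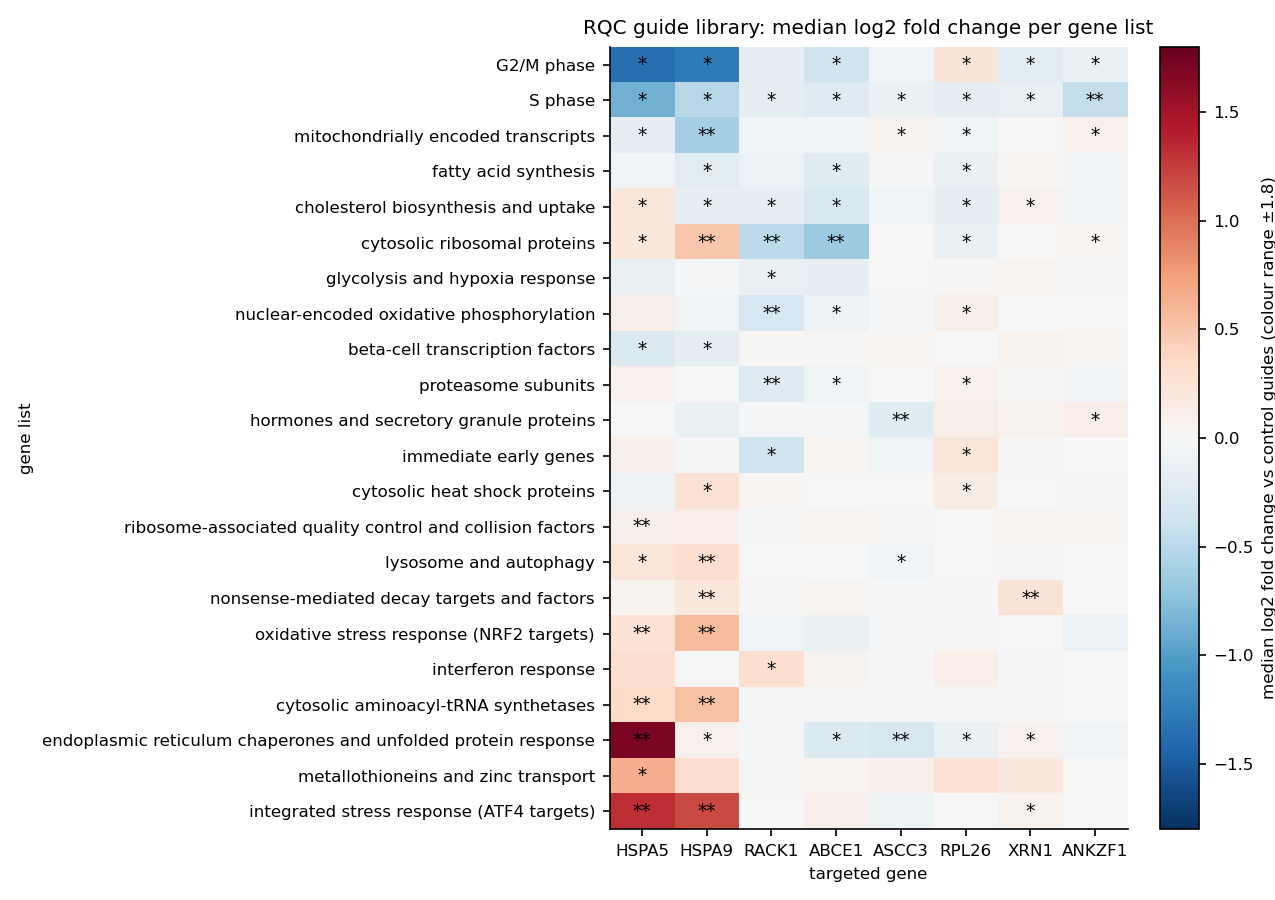
Median log2 fold change (color, from -1.8 to 1.8) of the members of each gene list called in any of them (vertical axis) in the 8 RQC targets with the most calls (horizontal axis). A single asterisk marks lists called by camera and a double one those also called with an estimated correlation, such as reticulum chaperones in HSPA5 (1.70) and ASCC3 (-0.30) and ribosomal proteins in HSPA9 (0.51) and ABCE1 (-0.66).

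Over all targets, camera called 235 of 1828 tests of a target and a list in the GWAS library and 170 of 1200 in the RQC library. With an estimated correlation 0 GWAS tests (72 at an unadjusted p under 0.05, where 91.4 are expected) and 20 RQC tests were called. Fry called 0 GWAS tests (154 at an unadjusted p under 0.05) and 46 RQC tests, 40 of them among the 170.

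In 17 RQC targets edgeR called 0 genes, and DESeq2 also called 0. In edgeR these targets had 92 to 518 genes at an unadjusted p under 0.05, where 614.9 are expected. All of these counts lay below the expected number. Fits of each target alone with the control, given above, called more pairs in all, but their calls in these 17 are not given here. Whether the spread pooled over all targets was too wide for these 17, so that changes were missed, thus stays open. The own transcript fell in 12 of these 17, among them EDF1, the collision sensor GCN1, its partner kinase EIF2AK4, NEMF, which tags stalled chains, and HBS1L, a partner of PELO in ribosome rescue. HSP90B1, a reticulum chaperone like HSPA5, fell by 0.99 ± 0.0913 log2 with 0 called genes (189 cells). These targets were chosen for mention after their values were seen.

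As a background, each control guide with enough cells was compared with the other control guides in the same way. The 6 GWAS guides gave 3 called genes in all and the 13 RQC guides gave 9. With the stricter guide call 4 GWAS guides could be tested and gave 35 called genes, and the 13 RQC guides gave 41.

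Profiles of targets were compared across genes, which are not independent replicates. ANKH and CEP68 correlated at r = 0.81 over 341 genes, GIPR and CEP68 at 0.72 and ANKH and GIPR at 0.69, each against separate control cells. Against the same control cells, targets with no effect gave 0.306, 0.301 and 0.334 in simulation. The covariances were 0.784, 0.465 and 0.426, against 0.0168, 0.0151 and 0.0111 simulated. Here and for the RQC pairs below, the dispersion in the simulation was fixed and not estimated from these counts. Simulated values can therefore be too high or too low. The simulation also drew each gene independently and repeated no choice of called genes. Genes that vary together by chance in which cells were assigned are thus absent from it. The excess over the simulated values therefore cannot tell a shared effect of the knockdowns from such chance. ANKH and CEP68 shared 12 called genes of the same sign, GIPR and CEP68 15 and ANKH and GIPR 42. MADD was at 0.20 with ANKH, 0.17 with GIPR and 0.08 with CEP68, and without replicate 2 at 0.04 with GIPR and -0.11 with CEP68. HSPA5 and HSPA9 correlated at 0.64 over 4051 genes (0.330 simulated with shared controls, covariance 0.295 against 0.0229). They shared 828 called genes of the same sign and 13 of opposite sign. RACK1 and ABCE1 were at 0.40, and at 0.44 against the same control cells (covariance 0.0453), and they shared 237 genes of the same sign and 13 of opposite sign. For this pair the simulation gave 0.418 (covariance 0.0229). For ASCC3 and RPL26 it gave 0.396 (covariance 0.0231), where the data had 0.0974 (0.00393) against the same control cells. The simulated values of the RQC pairs were thus too high to serve as values with no effect. HSPA5 and ASCC3 were at -0.01 and shared 3 genes of the same sign and 21 of opposite sign. The shared genes were called against the same control cells, and no count for targets with no effect was computed for them. All 6 pairs of the GWAS library and 15 of the RQC library were computed.

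ASCC2, PELO and ZZEF1 were targeted in both guide libraries. PELO, which rescues stalled ribosomes, was at -1.05 ± 0.166 log2 in the GWAS library (6 guides, 381 cells, n = 6) and -0.41 ± 0.161 in the RQC library (4 guides, 444 cells, n = 2). The difference of 0.63 had adjusted p = 0.0212 over the 3 targets (edgeR interaction). ZZEF1 was at -0.95 ± 0.102 (6 guides, 288 cells) and -2.02 ± 0.150 (2 guides, 229 cells), a difference of -1.08 with adjusted p = 0.000247 (edgeR). The difference for ASCC2 was 0.29 (adjusted p = 0.525, edgeR). None of these passed when adjusted over all genes (adjusted p = 0.9998, 0.99995 and 0.512 for ASCC2, PELO and ZZEF1 in edgeR), and guide numbers differed along with the libraries. The guides of a target also differed within a library. Of the GWAS guides of PELO, guide 1 left 3 UMIs in 107 cells, guides 2 and 3 were at -2.75 and -2.18, and guides 4, 5 and 6 at 0.04, 0.23 and 0.64. Its RQC guides lay between -2.62 and 0.48. The GWAS guides of ZZEF1 lay between -3.34 and 0.01, and its RQC guides were at -1.78 and -2.46, values per guide being chosen after they were seen. So the differences between libraries were not separated from the choice of guides.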

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

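The tests of G2/M genes in carriers, of IAPP, GAST and AC060765.1 taken singly, of the HNF4A transcript, of genes near the target and of the MPHOSPH9 guides were chosen only after the result was seen.

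GWAS replicate 5 stood apart from the other 6 GWAS samples in 4 measures, by a gap larger than expected for the highest or lowest of a group. Its total was 41682960 UMIs (144909010 to 212059648 in the others), its median share of mitochondrially encoded UMIs 1.20%, its median share of INS UMIs 2.39% and its mean number of targets carried per cell 3.02. In the same way 1 sample lay apart for 5 named genes. SLC30A8 in CEP68 cells was at 0.41 log2 in replicate 7, KCNK16 in its own target's cells at -2.81 in replicate 1, DCLK2 in MADD cells at -1.05 in replicate 1, and MT-ATP6 and MT-ND2 in MPHOSPH9 cells at 0.85 and 1.08 in replicate 6. Of 95 groups tested 9 had such a sample, where chance gives 5%. The own transcripts of PELO and ZZEF1 differed between the guide libraries, by 0.63 and -1.08 log2 (RQC minus GWAS) in a test of the interaction.

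GAST, LINC01924, IAPP and AC060765.1 each passed in 4 or more GWAS targets, in 29 pairs of target and gene. If a few control guides set the reference level, the changes should shrink against another reference, and with all other assigned cells as the reference 12 pairs of these genes passed and 10 of the 29 were kept in the same direction, while the 9 pairs of LINC01924 were under the filter. For IAPP this argues against the control guides, since at least 93.8% of the log2 change was kept in each of the 5 targets with more than 3 IAPP UMIs. In HNF4A cells the own transcript, at 0.0068 ± 0.125 log2, argues against the knockdown as well. In GCKR cells (3 GCKR UMIs in control cells) no knockdown could be measured. In carriers of the other 4 targets IAPP passed in none, at 0.34 log2 in KCNJ11, 0.30 in IRF2BP1, 0.10 in MADD and -0.27 in C17orf58. Carriers of KCNJ11, IRF2BP1 and MADD thus did not show the fall, although most genes called in MADD cells also passed in MADD carriers. An effect of the knockdown and chance in which cells were assigned were not separated in these 4 targets. GAST and AC060765.1 kept as little as 48.0% and 30.6%, so that for them the reference level and an effect of the knockdowns cannot be told apart.

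Lower G2/M genes in ANKH, GIPR and CEP68 could come from the knockdown, from control cells rich in such transcripts, or from few cycling cells among the assigned cells by chance. Against the control cells as the source, the medians kept 87.8% of their size on average (89.9%, 79.8% and 93.9%) with all other assigned cells as the reference. Over the 59 targets the size of the G2/M median rose as cell numbers fell (Spearman rho = -0.296, one-sided permutation p = 0.0114). The Pearson r was -0.333 (permutation p = 0.0016), and -0.341 without the 2 targets farthest from the median cell number. A chance draw of cells predicts this relation, but the 59 include the 3 targets that raised the question. Over the other 56 it was weaker (rho = -0.229, one-sided permutation p = 0.0438, and r = -0.257, permutation p = 0.0234, and -0.247 without the 2 farthest). The median was below 0 in 49 of the 59 targets. A knockdown that lowered both cell numbers and G2/M transcripts would give the same relation, so it does not decide between chance and the knockdown. In carriers the medians of ANKH, CEP68 and GIPR lay at the percentiles 15.3, 8.47 and 3.39 of all targets, while their own transcripts also fell by less than in assigned cells (-2.05, -1.48 and -1.99 log2, against -3.60, -2.59 and -3.57), so that a smaller effect of the knockdown cannot be told apart from chance with these cells, and what free RNA adds to such transcripts was not tested.

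Genes within 100000 bases of the target were called lower 15.4 times as often as other genes of the same fits, which is consistent with silencing that reaches past the targeted promoter, or with reads shared by overlapping genes for 7 of the 13 pairs, C12orf65 in MPHOSPH9 cells among them. C12orf65 was at -3.27 and -2.56 log2 with the MPHOSPH9 guides of at least 30 cells (guides 1 and 3), and at -1.64 with guide 2 (29 cells), with medians of the mitochondrially encoded transcripts of 0.38, 0.43 and 0.18. Whether these transcripts follow loss of C12orf65 or of MPHOSPH9 cannot be told apart, since each guide lowered both and guide 2, with the smallest change in all 3 measures, has few cells. No biological explanation beyond the guide target was tested for these 3 patterns.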

How the results depend on the processing

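The cells carrying a target's guides whatever else they carry, the control guides without the one with the most cells, and the GWAS samples without replicates 5 and 6 were chosen only after the result was seen.

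Scaling by DESeq2's size factors in place of TMM, the minimum of 20 CPM, DESeq2's test, no cell filter, the stricter cell filter and the minimum of 20 cells per sum kept the totals of each library, the counts of own transcripts that fell and the counts of the targets with at least 50 calls within 1.5 times. Own transcripts that fell numbered 20 to 38 in the GWAS library under all alternatives but the one with no filter on low counts, and 24 to 34 in the RQC library. In the GWAS library the 441 calls became 5972 with no filter on low counts (and 43 own transcripts fell, against 28), 247 with the stricter and 930 with the looser guide call, 876 with all other assigned cells as the reference, 116 with adjustment over all targets, 160 without the guide with the most cells of each target, 288 with limma-voom and 2857 in carriers. MADD, with 134, gave 426 with no filter on low counts, 252 with no replicate block in place of the pairing within samples, 784 with the looser guide call, 553 with the other reference, 0 with at most 150 cells per target (edgeR, 1190 at an unadjusted p under 0.05), 7 with adjustment over all targets, 10 without the top guide, 244 with voom and 2623 in carriers. ANKH, with 121, and GIPR, with 81, gave 365 and 257 with no filter, 20 and 43 with the stricter and 1 and 1 with the looser guide call, 27 and 18 with adjustment over all targets, 53 and 8 without the top guide, 4 and 1 with voom (all of them higher), and 0 and 0 in carriers (edgeR, 652 and 716 at an unadjusted p under 0.05), and ANKH gave 66 without replicates 5 and 6 together. CEP68, with 25, gave 192 with no filter, 4 at 20 CPM or with adjustment over all targets, 1 with no replicate block or the stricter guide call, 0 with the looser call (edgeR, 711 at an unadjusted p under 0.05), 2 with voom (both higher) and 3 in carriers. KCNJ11, with 9, gave 61 with no filter, 17 with at least 20 cells per sum, 5 with no replicate block, DESeq2 or the other reference, and 0 with the looser call (570) and voom (659). Of these 25 and 9 genes, 0 and 1 also passed in carriers. MPHOSPH9, with 12, gave 242 with no filter, 6 with no replicate block, 7 with at most 150 cells or without the top guide, 5 with adjustment over all targets and 25 in carriers. SND1, with 6, gave 101 with no filter, 1 at 20 CPM, 11 with the looser call, 3 with at most 150 cells and 17 in carriers. GCKR, with 5, gave 39 with no filter, 1 at 20 CPM, with the stricter call or without the top control guide, 2 with the other reference, at least 20 cells per sum, adjustment over all targets or carriers, and 0 with DESeq2, no replicate block, no top guide (edgeR, 732 and 633 at an unadjusted p under 0.05) and voom (570). With single samples left out, the calls ranged from 219 to 481 in all, from 6 to 161 in MADD, from 43 to 169 in ANKH and from 24 to 99 in GIPR.

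In the RQC library the 5874 calls became 2977 with adjustment over all targets, 2613 without the top guide and 8840 with the target and control alone in the fit. Adjustment over all targets gave 1308 in HSPA5, 649 in HSPA9, 437 in RACK1 and 359 in ABCE1, and leaving out the top guide 495 in HSPA9, 165 in RACK1 and 81 in ABCE1. RACK1 and ABCE1 gave 1589 and 1307 with the other reference, 500 and 365 with at most 150 cells, and 1952 and 1622 with the target and control alone. Carriers gave 2268 in HSPA9 and 1652 in RACK1. ASCC3, with 39, gave 64 with no filter, 65 with the other reference, 14 with at most 150 cells and 13 without the top guide. RPL26 (23), XRN1 (18) and ANKZF1 (13) gave 130, 75 and 118 with no filter, 75, 11 and 5 with DESeq2, 74, 28 and 5 with the looser call, 234, 73 and 20 with the other reference, 2, 6 and 1 with at most 150 cells, 5, 4 and 2 without the top guide, 74, 81 and 154 with the target and control alone and 159, 48 and 20 in carriers. XRN1 gave 10 at 20 CPM, ANKZF1 1 with the stricter call, and RPL26 and ANKZF1 40 and 27 with adjustment over all targets. The control guides' calls were 35 from 4 guides in the GWAS library, against 3 from 6, and 41 against 9 in the RQC library with the stricter guide call. The called gene lists fell from 235 to 0 (estimated correlation) and 0 (fry) in the GWAS library and from 170 to 20 and 46 in the RQC library.

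Similarity over all tested genes, in place of the called genes, was 0.34 for ANKH and CEP68, -0.0260 for MADD and CEP68, 0.50 for HSPA5 and HSPA9 and -0.00503 for ASCC3 and RPL26. Over the called genes with single samples left out, ANKH and CEP68 ranged from 0.71 to 0.84, MADD and CEP68 from -0.11 to 0.25, MADD and ANKH from -0.000371 to 0.35, HSPA5 and HSPA9 from 0.51 to 0.58, ASCC3 and RPL26 from -0.0439 to 0.0268 and HSPA5 and ASCC3 from -0.10 to 0.0806. With all control cells for both, HSPA5 and ASCC3 were at 0.0190.

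Some values changed sign. HNF4A's own transcript was at -0.0581 with no filter on low counts, from -0.0913 to 0.0786 with single samples left out, at -0.00463 with the other reference and at -0.0103 without the top control guide. TBC1D30 ranged from -0.0562 to 0.25 and was at -0.0892 in carriers, PAM was at -0.0154 with the stricter guide call, MACF1 at 0.12 without its top guide and ROBO1 at -0.0398 in carriers. IAPP in KCNJ11 cells was at 0.14 with the looser guide call. In carriers IAPP was at 0.34 in KCNJ11, 0.10 in MADD and 0.30 in IRF2BP1, DOCK5 at -0.0241 in ANKH, ALCAM at 0.0303 in MPHOSPH9 and KRT19 at 0.0787 in GCKR. In the RQC library GIGYF1 was at -0.00823 with no filter on low counts, -0.00755 with the looser guide call, -0.000301 with the target and control alone and -0.0190 in carriers, and from -0.12 to 0.12 with single samples left out. HSPH1 in HSPA9 cells ranged from -0.00542 to 0.85, and ETF1 was at 0.28 without its top guide. Over the named genes, 1574 of 2084 GWAS values kept direction and side of the threshold, 470 no longer passed, 22 newly passed and 18 changed sign, and 4291, 284, 7 and 7 of 4589 RQC values. The cause was not tested except where the alternative itself leaves fewer cells, samples or calls. Depth limits genes below about 5 CPM, which were not tested, and with 2 RQC samples a left-out sample gives values with no test. No value could be had for ANKH and CEP68 with at least 20 cells per sum, or for CEP68 and KCNJ11 without their top guide.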

Other observations

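The tests of ABCC8 genes in KCNJ11 carriers, of each own transcript in the other's carriers and of other splits over all 59 targets were chosen only after the result was seen.

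ABCC8 and KCNJ11 encode the regulatory and the pore subunit of the ATP-sensitive potassium channel that couples glucose to insulin release. In cells carrying ABCC8 guides whatever else but a control guide they carried (1026 cells, n = 7), 25 genes passed beyond ABCC8 itself, 7 higher and 18 lower. The membrane protein gene TSPAN1 rose by 0.72 ± 0.127 log2, and was at 0.72 ± 0.0856 in KCNJ11 carriers (964 cells, n = 7), where it also passed. Somatostatin (SST) was at -0.91 in ABCC8 carriers and -0.83 in KCNJ11 carriers, VAT1L at -0.95 and -0.56, and the phosphatase receptor PTPRD, which passed in both, at -0.22 and -0.21. All 25 genes had the same sign in KCNJ11 carriers, with a mean change of 0.265 in the direction of ABCC8, where ABCC8 itself had 0.427. The median of the other targets without KCNJ11, which share control cells with ABCC8, was 0.0468. In turn 13 genes were called in KCNJ11 carriers, of which ABCC8 itself (0.26) had the opposite sign in ABCC8 carriers, as the target there, and 11 of the other 12 had the same sign. These genes were chosen after their values were seen.

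A hypothesis is that loss of the shared channel changes these genes. KCNJ11 carriers without ABCC8 guides ranked 2 of the 59 other targets in the mean change, behind FOXA2 (0.343, from 70 carriers in 5 samples), so the test leaves this open. Cells that carried guides of both genes (27 cells) argue against themselves as the source, since 98.7% of the mean change in KCNJ11 carriers was kept without them. Repression reaching from 1 of these neighbouring genes to the other would lower the other's transcript, yet ABCC8 was at 0.26 in KCNJ11 carriers and KCNJ11 at 0.45 in ABCC8 carriers (the lower of the values is 0.259).

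ASCC3 acts in a complex with ASCC1, ASCC2 and TRIP4, and a hypothesis is that its loss lowers the genes that fell in ASCC3 cells. Genes that are RQC targets themselves, HSPA5 and HSP90B1 among them, were left out of this comparison. The other 35 had a median of -0.47 log2 in ASCC3, -0.04 in TRIP4 (26 below 0), -0.03 in ASCC1 (25 below 0) and 0.03 in ASCC2, whose own transcript did not pass. TRIP4 and ASCC1 lay at the percentiles 15.4 and 28.2 of the other targets. The bounds set before the test asked for both below 10 if the complex were the cause and both above 25 if not, and ASCC1 alone lay above 25, so it does not decide.

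Among the genes higher in MADD cells were several known best as proteins that the liver secretes, namely VTN, SERPINA6, SERPINA1 (0.63 log2), RBP4 (0.62), TTR (0.55) and APOC3 (0.48). These were chosen after their values were seen and were not tested as a group. Of them, TTR is also in the list of hormones and granule proteins used here, and RBP4 in that of markers of other islet cells.

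Target and control sums were exchanged within samples to see how often other splits gave as many called genes. This asks only which sum was the target's, and chance in which cells were assigned, raised above for the G2/M genes of ANKH, GIPR and CEP68, stays open. Taken singly, chance in the split can be excluded for MADD (134 genes, 1 of 32 splits, at most 2 in the others), ANKH (121, 1 of 32, at most 1), GIPR (81, 1 of 32, at most 1) and MPHOSPH9 (12, 1 of 32, at most 1), where 1 of 32 is the smallest share possible. These were among the 8 targets with the most calls of 59, a choice that the share does not count. In 470 other splits, 8 drawn from each of the 59 targets (7 where there are no more), 5 gave at least 12 genes and the highest, in WSCD2, gave 56. So for MPHOSPH9 chance cannot be excluded once that choice is counted, and for MADD, ANKH and GIPR it was not excluded with this number of splits, although none of the 470 gave as many genes. The highest of a draw depends on its size, and in a full count of these splits, too long to keep among the tests, it came close to the 81 of GIPR without reaching it. It cannot be excluded for SND1 (6 genes, 2 of 32 splits, up to 21 in another). The splits were too few for a share under 0.05 in CEP68 (25 genes, 1 of 8 splits, highest other 1), KCNJ11 (9, 1 of 16, highest other 3) and GCKR (5, 2 of 16, highest other 6).

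The labels give about 100000 cells profiled per sample and a share of cells positive for the guide vector's BFP of under 20%, whereas the matrices hold 709 to 10468 barcodes and a GWAS cell carried a mean of 2.47 to 3.02 targets. FOXA2 had 87 carriers without a control guide, and 8 cells were assigned to it.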
